A study of Arabidopsis thaliana with 9 samples.

How the data were processed

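The series holds 9 RNA-seq libraries from the above-ground parts of Arabidopsis thaliana plants, 3 each of WT, cuc2-3 and CUC2gm-4. Per the labels' protocols total RNA was selected for messenger RNA and made into stranded single-end libraries with a size selection at 230 bp for the Ion Torrent Proton, which reads DNA synthesis from released protons. Each library has its own deposited file of whole-number read counts, with 33602 gene models per file. Per the file headers the authors counted reads with sam2pkm, removed reads that align equally well to more than a single place, and gave the reads parsed and mapped; mapped reads minus removed reads equal the sum of each file's counts. The genome build is TAIR10 per the submitters' processing notes. The aligner, the strand setting of the counting and any trimming are not given in the sources used here.

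Mapping rates ran from 92.2% in cuc2-3 3 to 96.6% in cuc2-3 2, and total counts from 17361433 to 27734410 per library. A count of 3 then corresponds to between 0.108 and 0.173 CPM, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of a genotype differed far beyond counting noise (a chi-square of 34.9 to 109 per gene), so no library was treated as a repeat of another. Removing reads with several best placements lowers the counts of repeated sequences and recent gene copies, and counting without regard to strand would mix overlapping genes.

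Gene symbols came from the TAIR10.1 reference, which held 32835 of the 33602 identifiers and gave a symbol to 10654. The files give no coordinates and the build named by the submitters is TAIR10, so positions were taken from the TAIR10.1 reference by identifier and are named as such; 6321 of the 32835 model lengths (19.3%) equal the span of the gene there and 9966 equal its summed exons. Plastid genes have no names in that reference and are given as counts of genes or by identifier.

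Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept at a CPM of at least 1 in at least 3 libraries, with CUC2 kept whatever its counts, which left 18291 genes: 18198 nuclear, 77 plastid and 16 mitochondrial. TMM factors were used, a quasi-likelihood model with genotype as its single factor was fitted to all 9 libraries so that they share an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg within each of the 3 comparisons at a threshold of 0.05 with no minimum fold. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM of the CUC genes are scaled by the library total, and those called normalised use the TMM factors.

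Genes to be named were set before the data were examined: up to 12 per direction with the largest change among those that passed and lay apart in the 2 genotypes, the genes with the smallest p until 5 were named in a direction, list members that passed, and the CUC and miR164 genes. A gene of the lists is counted in the totals of its list but is not reported here. Other genes named as examples of a list, those tied to the replicate block, and the clock genes were chosen after their values were seen. The 27 gene lists were also fixed in advance, with 407 of their 413 members matched to the files; 25 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry from limma 3.58.1. Fry, which asks whether a list moves on balance in a direction, gave no adjusted p below 0.27, and its mixed test passed for the stomatal lineage list alone, in CUC2gm-4 against WT (0.0039).

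Genotypes share the replicate numbers 1 to 3 in the labels, which do not say what a number stands for. After subtracting genotype means, libraries with the same number correlated with r from 0.198 to 0.586 in all 9 pairs. Libraries with other numbers correlated with r from -0.477 to 0.188 in 18 pairs. Each library correlated best with its own number in 18 of 18 settings, which are not independent, so the numbers pair the libraries in these data. For WT 1 it was nearly a tie, with r of 0.198 to cuc2-3 1 and 0.188 to cuc2-3 2. The fit with the replicate number as a block was planned as an alternative, and its values stand beside the results that it changes. The common biological coefficient of variation was 0.237 without and 0.177 with the block.

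The procedure was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed by a fold of 2 and 100 by a fold of 4. The 23 cell division genes were changed by a fold of 1.5 in the same draws. Of the genes changed by a fold of 2 and of 4, it recovered 30 and 85 for cuc2-3 against WT (among 18154 genes). It recovered 37 and 91 for CUC2gm-4 against WT (18158 genes), and 32 and 89 for CUC2gm-4 against cuc2-3 (18162 genes). Unchanged genes called numbered 3, 11 and 9. The simulated libraries were drawn independently and leave out the pairing by replicate number, so these figures need not hold for the real libraries.

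The alternatives planned in advance were other size factors, library totals, upper-quartile factors, DESeq2 1.42.0, limma-voom, no or a stricter count minimum (CPM 2), a fold threshold of 1.5, only the genotypes compared, organelle genes removed, the replicate block, and each library left out in turn. After seeing the data the clock index as a covariate, the removal of replicate 3 of every genotype and leaving out libraries in the blocked fit were added. Correlations between comparisons that share the WT libraries were set beside 100 simulations of unchanged groups. Single values were compared with 2-sided exact permutation tests, which cannot go below 0.1 with 3 against 3. Figures were drawn with Python 3.11.15.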

Results

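RNA was sequenced from the above-ground parts of Arabidopsis thaliana plants at 21 days of age, all in the Col-0 background. The plants were raised on soil at 21 °C and 65% relative humidity under short days with 8 h of light. The 9 libraries fall into 3 genotypes with 3 libraries each, namely wild type (WT), cuc2-3 and CUC2gm-4, and are named here by genotype and replicate number. CUC2 encodes a NAC transcription factor that acts at the boundaries between organs and in the teeth of the leaf margin, and the series asks how the CUC factors act while leaves develop. Total counts were 18384626, 17361433 and 22934969 in WT 1, 2 and 3, then 22835829, 18039106 and 27734410 in cuc2-3 1, 2 and 3, and 24442714, 18934648 and 23502408 in CUC2gm-4 1, 2 and 3. The labels do not say whether the replicates came from separate sets of plants, so the p-values measure only the spread between these samples. An index of clock genes, given below, ranged over 2.65 to 4.09 within a genotype. This argues against all 3 libraries of a genotype being technical repeats of a single RNA sample. Whether single pairs of libraries are such repeats stays open.

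CUC2 (AT5G53950, chromosome 5, 21901704 to 21903854 on the minus strand of the TAIR10.1 reference) was scarce in WT and in cuc2-3 and abundant in the libraries labelled CUC2gm-4. WT held 13, 53 and 55 counts, a mean of 2.05 ± 1.21 CPM (counts scaled by the library total; SD, n = 3). The cuc2-3 libraries held 38, 11 and 23 counts, 1.03 ± 0.556 CPM, and those labelled CUC2gm-4 held 779, 656 and 1062 counts, 37.2 ± 7.03 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment CUC2 rose in the libraries labelled CUC2gm-4, with a log2 fold change of 4.12 (SE 0.42, adjusted p = 0.0077) against WT and 5.06 (SE 0.45, adjusted p = 0.0018) against cuc2-3. Between cuc2-3 and WT the log2 fold change was -0.95 (SE 0.46) with an adjusted p of 1.0, and it was -1.50 without cuc2-3 1 and -0.61 without WT 2, the ends of its range with single libraries left out. A 2-sided exact permutation test of the CPM values gave p = 0.3 there. It gave an exact p = 0.1 for either comparison with CUC2gm-4, the smallest p that 3 libraries against 3 allow. The series describes both mutants as loss-of-function lines, and the CUC2 level in the libraries labelled CUC2gm-4 goes against that description. The level in cuc2-3 does not tell it from WT. Without CUC2gm-4 3 the log2 fold change against WT was 3.96 with an adjusted p of 0.0591, the highest of a range from 1.6e-20 over all alternatives. Leaving out replicate 3 of every genotype, a choice made after seeing the data, gave 4.72 against cuc2-3 with an adjusted p of 0.0862, the highest of a range from 1.9e-29.

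**Figure D1:**
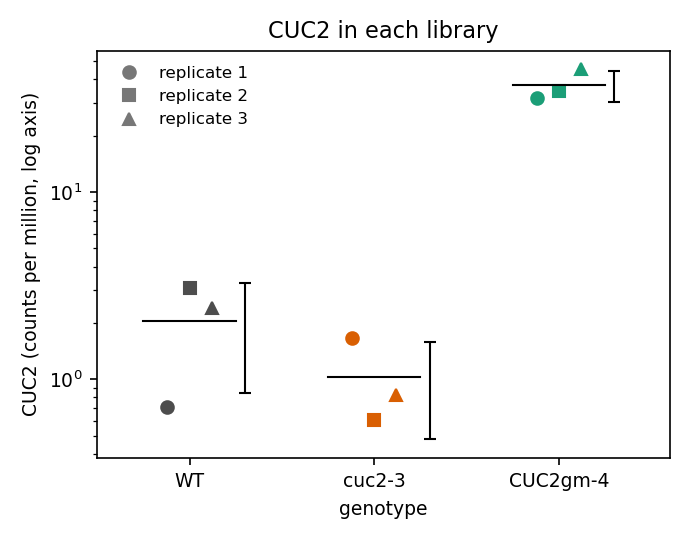
CUC2 in CPM (counts scaled by the library total), on a log axis, for each of the 9 libraries, with the genotype mean as a line and the SD (n = 3) as a bar to its right. The libraries labelled CUC2gm-4 lie around a mean of 37.2 CPM, above every library of WT (mean 2.05) and cuc2-3 (mean 1.03).

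The other CUC genes passed the threshold in no comparison. CUC3 (AT1G76420), a paralogue that also marks organ boundaries, had 1.71 ± 1.03 CPM in WT, 2.53 ± 0.271 in cuc2-3 and 2.62 ± 0.308 in the libraries labelled CUC2gm-4. Its log2 fold changes were 0.59 (SE 0.38) for cuc2-3 against WT, 0.57 (SE 0.38) for CUC2gm-4 against WT and -0.025 (SE 0.37) for CUC2gm-4 against cuc2-3, none past the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The values against WT moved with the WT libraries used, at 0.26 and 0.23 without WT 1 and 1.06 and 1.04 without WT 2. That against cuc2-3 turned positive when library totals replaced the normalisation factors (0.052). CUC1 (AT3G15170) lay below the count minimum, with 47, 56 and 30 counts summed over the 3 libraries of WT, cuc2-3 and CUC2gm-4. In numbered order it had 0.490, 1.27 and 0.698 CPM in WT, 0.701, 1.55 and 0.433 in cuc2-3 and 0.286, 0.898 and 0.255 in CUC2gm-4. It was thus lower in CUC2gm-4 than in each same-numbered library. With no count minimum its log2 fold changes for CUC2gm-4 were -0.86 (SE 0.61) against WT and -0.97 (SE 0.61) against cuc2-3, neither past the threshold. The precursors of miR164, the microRNA that cleaves CUC1 and CUC2 transcripts, were not detectable at this depth in messenger RNA libraries: MIR164a had 0 counts in all libraries, MIR164b at most 3 in a library and MIR164c at most 1.

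The first comparison asked what differs when cuc2-3 is set against WT. MRD1 (AT1G53480), a gene named for its lower transcript level in the mto1 methionine mutant, rose from 0.0929 ± 0.0443 normalised CPM in WT to 35.1 ± 4.54 in cuc2-3 (SD, n = 3). SADHU3-2 (AT3G42658), a copy of the Sadhu family of retroelements annotated as a pseudogene, rose from 0.155 ± 0.142 to 83.8 ± 2.78 normalised CPM. AT2G44970, which encodes an alpha/beta-hydrolase, rose from 7.31 ± 0.975 to 32.4 ± 2.15, and TRM21 (AT5G43880), a member of the TON1 Recruiting Motif family, fell from 25.7 ± 2.95 to 6.23 ± 1.34. In all 4 genes the 3 cuc2-3 libraries lay apart from the 3 WT libraries.

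These 4 genes, 3 higher and 1 lower, were those that passed among 18291 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. An unadjusted p below 0.05 was found for 358 genes, and for 682 with the replicate number as a block, where 914.55 are expected by chance. The unblocked fit counts differences between replicate numbers as spread, which can lower its count. The blocked count was below the expected number too, so that spread does not account for the whole shortfall. Neither count shows that the genotypes do not differ. The log2 fold changes were 8.56 (SE 0.32, adjusted p = 6.3e-07) for MRD1, 9.16 (SE 0.55, adjusted p = 4.8e-05) for SADHU3-2, 2.15 (SE 0.16, adjusted p = 0.00025) for AT2G44970 and -2.04 (SE 0.19, adjusted p = 0.0020) for TRM21. Because WT held only 2, 2 and 1 counts of MRD1 and 3, 5 and 0 of SADHU3-2, their ratios are better read from summed counts. MRD1 was 412-fold higher in cuc2-3 with a 95% counting interval of 176 to 1269, and SADHU3-2 603-fold higher with an interval of 306 to 1398. DESeq2 called 14 genes, 13 of them higher. SADHU3-2 was above the count minimum only in the 3 cuc2-3 libraries, so it was not tested when any of these was left out. Reads that align equally well to other copies of its family were removed, which can lower its counts. Whether reads of less similar copies were placed on it was not tested.

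On the TAIR10.1 reference MRD1 lies on chromosome 1 (19963047 to 19964712, minus strand), AT2G44970 on chromosome 2 (18548813 to 18552171, minus strand), SADHU3-2 on chromosome 3 (14749400 to 14750294, minus strand) and TRM21 on chromosome 5 (17639776 to 17643982, minus strand). MRD1 shares 1446 bp with HEI10, a meiotic gene, and 1039 bp with AT1G07887, both on the opposite strand, and whether the authors' counting used the strand is not given in the sources used here, so the MRD1 value is uncertain to that extent. HEI10 itself had a log2 fold change of 0.45 (SE 0.19) in cuc2-3 and 0.71 (SE 0.19) in the libraries labelled CUC2gm-4, neither past the threshold, and AT1G07887 was not among the genes tested. AT3G29644, a long non-coding RNA with 471 bp in antisense to AT3G29642, came next in cuc2-3 with a log2 fold change of 2.42 (SE 0.34, adjusted p = 0.088), short of the threshold in edgeR, and carries the same uncertainty. It passed in DESeq2 (5.6e-08) and with no count minimum (0.0065), in a range of 5.6e-08 to 0.722 over all alternatives. The genes with the smallest p-values among those lower in cuc2-3 that did not pass were AT3G05730, a defensin-like gene (-1.06, SE 0.27), AT5G57760 (-2.59, SE 0.68, and -1.55 without WT 3), AT5G41650 of the glyoxalase family (-0.77, SE 0.21) and AT5G56910 of the cystatin type (-0.63, SE 0.18).

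Among the gene lists fixed in advance, 4 of 25 moved in cuc2-3 against WT by camera at a preset correlation of 0.01, and 0 did with an estimated correlation. Touch and immediate early genes, which answer to mechanical and wounding stimuli within minutes, fell as a list: 11 of 12 members had negative values with a median log2 fold change of -0.48, for example STZ (-1.0), CZF1 (-1.0), ERF6 (-0.91) and RHL41 (-0.82). The touch list's camera adjusted p was 6.6e-06 (adjusted p = 0.615 with an estimated correlation). Its mean log2 CPM was lower in cuc2-3 in only 2 of 3 same-numbered pairs. A 2-sided exact permutation test of that mean, which ignores the pairing, gave p = 0.4. With the clock index as a covariate, a choice made after seeing the data, the list's median was -0.335. STZ was at -2.06 without cuc2-3 2, -0.57 without cuc2-3 3 and -0.64 without WT 1, ERF6 at -1.68 and -0.59 without cuc2-3 2 and cuc2-3 3, and CZF1 at -1.52 without cuc2-3 2. Heat and protein folding genes rose as a list, 8 of 9 members positive with a median of 0.37, among them HSFA2 (1.18, and 0.54 without cuc2-3 1) and HSP101 (0.72). Its adjusted p was 0.0025 (adjusted p = 0.442 with an estimated correlation). Glucosinolate genes rose, 14 of 16 positive with a median of 0.40, among them MYB34 (0.52), CYP83A1 (0.51) and CYP79F1 (0.48) but not MYB51 (-0.68). The adjusted p was 0.0025 here too (adjusted p = 0.817 with an estimated correlation). Without WT 1 CYP83A1 was at 0.27 and CYP79F1 at 0.20, and without WT 2 CYP79F1 was at 0.74. Organ boundary genes rose, 10 of 14 positive with a median of 0.22, among them LOB (0.60, and 0.35 without WT 1) and BOP2 (0.54). The adjusted p was 0.018 (adjusted p = 0.615 with an estimated correlation).

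Of the 347 tested members of all lists, 0 passed edgeR's quasi-likelihood test over all genes, 0 passed in DESeq2 and limma-voom, 8 had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone. With the replicate number as a block 4 touch genes (RHL41, STZ, ERF6 and CZF1), CBF1 and CBF2, HSP101 and the brassinosteroid gene ROT3 passed when adjusted over the list alone. The lists of abscisic acid, cold and drought genes (lower, adjusted p = 0.0073 against 0.081) and of KNOX, BELL and shoot meristem genes (higher, adjusted p = 0.034 against 0.102) also passed with the block, and neither did with the block and an estimated correlation (adjusted p = 0.683 and 0.625 with an estimated correlation). Without cuc2-3 1, 0 lists passed, with an adjusted p of 0.0695 for touch, 0.177 for heat, 0.0695 for glucosinolate and 0.177 for organ boundary genes. The glucosinolate and organ boundary calls also ended without WT 1 (0.429 and 0.794) or cuc2-3 2 (0.0839 and 0.155), and the heat call without WT 3 (0.0526). Without WT 2, WT 3 or cuc2-3 3, 8, 7 and 7 lists passed. Over all alternatives the adjusted p ranged from 3.6e-21 to 0.983 for touch, from 0.00013 to 0.587 for heat, from 6.4e-08 to 0.983 for glucosinolate and from 0.00013 to 0.983 for organ boundary genes. The other 21 lists had adjusted p-values from 0.081 to 0.990, and the median and the test differed in sign for leaf polarity, gibberellin, jasmonate and photosynthesis genes.

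**Figure D2:**
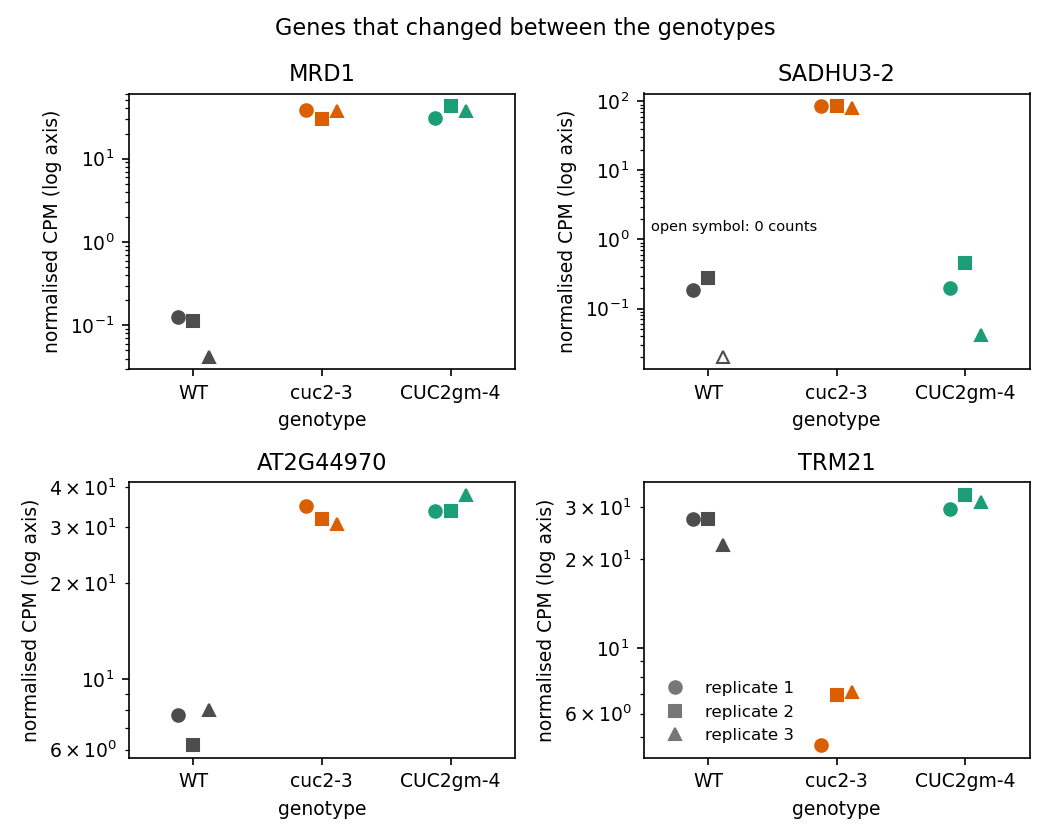
Normalised CPM of MRD1, SADHU3-2, AT2G44970 and TRM21 in each of the 9 libraries, on log axes, with an open symbol for a library at 0 counts, drawn at the foot of the axis. MRD1 and AT2G44970 are higher in both mutant genotypes than in WT, while SADHU3-2 and TRM21 stand apart in cuc2-3, at 83.8 and 6.23 CPM on average.

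The second comparison set the libraries labelled CUC2gm-4 against WT. MRD1 rose to 36.8 ± 6.05 normalised CPM from 0.0929 ± 0.0443 in WT, and AT2G44970 rose to 35.1 ± 2.41 from 7.31 ± 0.975 (SD, n = 3), next to the rise of CUC2 itself. SADHU3-2 stayed near the floor with 15 counts in all 3 libraries labelled CUC2gm-4 and 8 in WT, and TRM21 was at 31.2 ± 1.81 against 25.7 ± 2.95 normalised CPM, a difference that did not pass. MRD1, AT2G44970 and CUC2, all higher, were the 3 genes that passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with log2 fold changes of 8.63 (SE 0.32, adjusted p = 5.8e-07) for MRD1 and 2.26 (SE 0.16, adjusted p = 0.00023) for AT2G44970. MRD1 was 443-fold higher by summed counts, with a 95% counting interval of 190 to 1366. An unadjusted p below 0.05 was found for 1185 genes, and for 2000 with the replicate number as a block, where chance gives 914.55. DESeq2 called 81 genes, 44 higher and 37 lower.

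With the replicate number as a block 35 genes passed, 17 higher and 18 lower, of which 24 are nuclear and 11 plastid-encoded. AGO9, an Argonaute protein known for silencing transposable elements in ovules, was at 7.72 ± 0.703 normalised CPM against 0.928 ± 0.579 in WT (log2 fold change 3.01, SE 0.48, adjusted p = 0.173; block 3.11, adjusted p = 0.020; no count minimum 0.0088; DESeq2 3.9e-07, in a range of 3.9e-07 to 0.841 over all alternatives). RHL41 (-2.01, SE 0.37, adjusted p = 0.251; block adjusted p = 0.020), CBF1 (-2.07, SE 0.39, adjusted p = 0.251; block adjusted p = 0.034) and CBF2 (-1.63, SE 0.46, adjusted p = 0.609; block adjusted p = 0.034), zinc finger and cold response transcription factors, passed with the block and not in the unblocked edgeR test. RHL41 and CBF1 also passed in DESeq2 (0.00043 and 0.0012). The 3 had ranges over all alternatives of 0.00043 to 1.0, 0.0012 to 1.0 and 0.034 to 1.0. ERF104, CAF1a, PR4, DIC2 and the reticulon family gene AT3G61560 (-1.72, SE 0.28, adjusted p = 0.187), all lower, and AT3G29644 (2.51, SE 0.34, adjusted p = 0.058) and the pseudogene AT2G07080 (1.29, SE 0.18, adjusted p = 0.058), both higher, also passed with the block. The last 3 passed as well in DESeq2 and with no count minimum, AT3G29644 and AT2G07080 with the clock index as a covariate (0.0481 and 0.0395), and AT2G07080 without CUC2gm-4 2 (0.0399). Over all alternatives the adjusted p ranged from 2.1e-05 to 0.841 for AT3G61560, 8.8e-09 to 0.328 for AT3G29644 and 1.8e-07 to 0.440 for AT2G07080. AT2G40960 (-0.95, SE 0.18) and the lipid transfer protein gene LTP (-0.94, SE 0.18) passed in edgeR neither with nor without the block, while DESeq2 called both (0.0020 and 0.0024, the lowest of ranges reaching 1.0). The blocked count of 35 was 6, 21, 94, 58, 67, 4 and 6 without WT 1, WT 2, cuc2-3 1, cuc2-3 2, cuc2-3 3, CUC2gm-4 1 and CUC2gm-4 2, and the count of 3 became 5 without WT 3 and 8 without cuc2-3 3.

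Touch and immediate early genes fell as a list in the libraries labelled CUC2gm-4 against WT, 10 of 12 members negative with a median log2 fold change of -1.16. The camera adjusted p was 1.4e-10 (adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone, 4 members fell: RHL41 (-2.01), STZ (-2.06), WRKY40 (-1.82) and CZF1 (-1.34), and 9 did so with the replicate block, where ERF5, ERF6, WRKY33, WRKY46 and SZF1 were added. DESeq2 called WRKY40 over all genes (0.0069, the lowest of a range reaching 1.0). Photosynthesis genes fell as a list, 19 of 19 negative with a median of -0.35, for example RBCS2B (-0.61), CAB1 (-0.47) and LHCB3 (-0.39). The adjusted p was 1.6e-06 (adjusted p = 0.518 with an estimated correlation of 0.73), and without WT 1 RBCS2B was at -0.23 and CAB1 at -0.080. Abscisic acid, cold and drought genes fell, 13 of 16 negative with a median of -0.26, where CBF1 and CBF2 fell when adjusted over the list alone and COR15B, DREB1A and CYP707A3 also did with the block. For that list the adjusted p was 0.0021 (adjusted p = 0.518 with an estimated correlation). Heat and protein folding genes rose, 8 of 9 positive with a median of 0.57, among them HSFA2 (1.41), HSP90.1 (0.99) and HSP101 (0.71), with an adjusted p of 0.0021 (adjusted p = 0.452 with an estimated correlation).

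Over all genes 1 of the 347 list members passed edgeR's quasi-likelihood test, namely CUC2, against 44 with an unadjusted p below 0.05, 5 in DESeq2, 1 in limma-voom and 4 with the replicate block. Outside these lists ERL1 (0.64) and ERL2 (0.55), receptor kinases that restrain stomatal density, rose when adjusted over the list alone. MYB51 (-1.28), a regulator of indole glucosinolates, and WOX5 (-1.45), known from the root stem cell niche, fell when adjusted over the list alone. The stomatal lineage list as a whole had 9 of 12 members negative (adjusted p = 0.062). HSP101, GA20OX1 (-1.01), RBCS2B, SAG21 (-1.50) and NAC6 (-1.64) were among the members that passed with the block, and not without it, when adjusted over the list alone. With the block the lists of auxin response (lower, adjusted p = 0.024), organ boundary (higher, adjusted p = 0.019, with MYB117 and CYP78A5 passing when adjusted over the list alone) and senescence genes (lower, adjusted p = 0.039) also passed, against 0.051, 0.051 and 0.054 without it. None of these 3 passed with the block and an estimated correlation (adjusted p = 0.791, 0.584 and 0.50 with an estimated correlation). Without WT 1 the photosynthesis and the abscisic acid, cold and drought calls ended (0.165 each), and the heat call ended without WT 3 (0.0519) and, chosen after seeing the data, without replicate 3 of every genotype (0.0761). The number of lists went from 4 to 8 without cuc2-3 2 and to 9 without CUC2gm-4 3. Over all alternatives the adjusted p ranged from 3.0e-19 to 0.468 for touch, 3.9e-09 to 0.630 for photosynthesis, 1.4e-06 to 0.726 for abscisic acid, cold and drought and 0.00042 to 0.452 for heat genes. The other 21 lists had adjusted p-values from 0.051 to 0.996, and the median and the test differed in sign for auxin synthesis and transport, gibberellin, circadian clock and glucosinolate genes.

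The third comparison set the libraries labelled CUC2gm-4 against cuc2-3. SADHU3-2 fell from 83.8 ± 2.78 to 0.230 ± 0.205 normalised CPM, a log2 fold change of -8.55 (SE 0.51, adjusted p = 9.8e-05), and by summed counts it was 367-fold higher in cuc2-3 with a 95% counting interval of 222 to 656. TRM21 rose from 6.23 ± 1.34 to 31.2 ± 1.81 (2.32, SE 0.19, adjusted p = 0.0012), and CUC2 rose as given above. These 3 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 25 calls in DESeq2, 12 higher and 13 lower. An unadjusted p below 0.05 was found for 682 genes, and for 1351 with the replicate number as a block, where chance gives 914.55. MRD1 (log2 fold change 0.07) and AT2G44970 (0.12) did not pass, with an adjusted p of 1.0 each, and the sign of the MRD1 value turned without cuc2-3 2 (-0.033) or CUC2gm-4 2 (-0.051).

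AGO9 (3.66, SE 0.51, adjusted p = 0.089; block adjusted p = 0.013) and the transcribed pseudogene AT3G30122 (1.84, SE 0.26, adjusted p = 0.091; block adjusted p = 0.042) passed with the block and not in the unblocked edgeR test. Both also passed in DESeq2, and AGO9 in limma-voom (0.0322), with no count minimum (0.0015), with only the genotypes compared (0.0213) and without WT 1 (0.0380) or WT 3 (0.0146). Over all alternatives AGO9 ranged from 1.5e-10 to 0.669 and AT3G30122 from 2.7e-06 to 0.999. The block brought the count from 3 to 7 genes, with AT4G11290, a peroxidase gene also called by DESeq2 (0.0058), and PR4, a pathogenesis-related gene, among those lower. PR4 was at -1.13 (-0.67 without cuc2-3 2 and -1.71 without CUC2gm-4 2). That blocked count was 4 without WT 2, 2 without cuc2-3 3 and 3 without cuc2-3 2, CUC2gm-4 1, CUC2gm-4 2 or CUC2gm-4 3, and the unblocked count was 1 without replicate 3 of every genotype. Lower in the libraries labelled CUC2gm-4 but short of the threshold in edgeR were AT1G60110, a lectin gene (-3.05, SE 0.48), UGT72E1, a glucosyltransferase acting on lignin precursors (-1.04, SE 0.18), LUP1, a lupeol synthase (-1.12, SE 0.20), and LTP (-0.98, SE 0.18). DESeq2 called all 4, with adjusted p-values of 0.00090, 0.00036, 0.0014 and 0.0020 that are the lowest of ranges reaching 1.0 over all alternatives. Adjusted over the list alone YUC1 (1.29, SE 0.31), an auxin synthesis enzyme, rose. MYB117 (1.80), YUC4 (0.75) and CDKB1;1 (0.62) were among the higher members that the block added. Among those lower, RBCS2B (-0.61), BGL2 (-1.55), RHL41 (-1.19), WRKY40 (-1.13, and -1.72 without CUC2gm-4 2), MAM1 (-0.60), CYP79F1 (-0.78) and XCP1 (-0.63) were added.

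Photosynthesis genes fell as a list in the libraries labelled CUC2gm-4 against cuc2-3, 19 of 19 negative with a median log2 fold change of -0.39, for example RBCS2B (-0.61, and -0.37 without cuc2-3 1), LHCB3 (-0.45) and LHCA4 (-0.45). The camera adjusted p was 3.0e-08 (adjusted p = 0.890 with an estimated correlation). Glucosinolate genes fell, 15 of 16 negative with a median of -0.29, among them CYP79F1 (-0.78), MYB29 (-0.63) and MAM1 (-0.60), the last 2 at -0.42 and -0.35 without CUC2gm-4 1. The adjusted p was 0.00040 (adjusted p = 0.890 with an estimated correlation). Touch and immediate early genes fell, 10 of 12 negative with a median of -0.42 and an adjusted p of 0.0043 (adjusted p = 0.890 with an estimated correlation). Anthocyanin and flavonoid genes fell, 10 of 11 negative with a median of -0.26, among them TT5 (-0.47, and -0.21 without cuc2-3 1), with an adjusted p of 0.047 (adjusted p = 0.890 with an estimated correlation). DFR of that list was at -0.35, with values from -0.86 to -0.087 when single libraries were left out. Cell division genes rose, 14 of 23 positive with a median of 0.12, among them CDKB1;1 (0.62), CYCD3;1 (0.45) and CYCB1;1 (0.44), with an adjusted p of 0.038 (adjusted p = 0.579 with an estimated correlation).

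With the replicate block the anthocyanin and cell division calls ended (0.052 each) and abscisic acid, cold and drought genes passed (lower, adjusted p = 0.037; adjusted p = 0.826 with an estimated correlation). Both calls also ended with the clock index as a covariate (0.0686 for anthocyanin and 0.0632 for cell division genes), a choice made after seeing the data. Over all genes 1 of the 347 list members, CUC2, passed edgeR's quasi-likelihood test, against 34 with an unadjusted p below 0.05, 1 in DESeq2 and 1 in limma-voom. Without CUC2gm-4 1 the photosynthesis call alone of these 5 was kept, with 0.660 for glucosinolate, 0.386 for touch, 0.516 for anthocyanin and 0.0897 for cell division genes. The touch call also ended without CUC2gm-4 3 (0.192) and turned in direction without cuc2-3 2 (0.828). The anthocyanin call ended without cuc2-3 1 (0.179) or CUC2gm-4 2 (0.396), and the cell division call without cuc2-3 2 (0.0898), cuc2-3 3 (0.0580) or CUC2gm-4 2 (0.156). Over all alternatives the adjusted p ranged from 2.7e-11 to 0.993 for photosynthesis, 1.2e-14 to 0.993 for glucosinolate, 2.6e-10 to 0.993 for touch, 5.2e-09 to 0.993 for anthocyanin and 0.0080 to 0.579 for cell division genes. The other 20 lists had adjusted p-values from 0.091 to 0.955. Their median and test differed in sign for organ boundary, auxin synthesis and transport, gibberellin, iron and nutrient status and trichome genes. The lists of CUC genes and of root markers held 2 and 4 tested genes, too few for the list test.

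Both mutant genotypes shared 2 genes called higher against WT, MRD1 and AT2G44970, and 0 called lower in edgeR's quasi-likelihood test, where DESeq2 shared 8 calls and the unadjusted counts are given above. Independent lists of these sizes would share 0.00049 genes, and simulated unchanged groups against shared WT libraries shared 0.04 on average. Across the 18291 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with Pearson's r = 0.614, against 0.505 ± 0.0092 in 100 simulations with no change. The covariance was 0.0715 against 0.0499 ± 0.0013 simulated, a difference of 0.0216. With single libraries left out r ranged from 0.449 without cuc2-3 3 to 0.745 without WT 3, and its jackknife SD over the libraries was 0.235. With the replicate block r was 0.625 and the covariance 0.0708. The sign was the same in 68.1% of genes against 66.9% simulated. The 3 WT libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The simulated libraries were drawn independently and so leave out the pairing of libraries by replicate number, and no simulation with that pairing was run.

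Plastid transcripts took a larger share of counts in both mutant genotypes than in WT. Plastid-encoded genes took 0.118% ± 0.0092 of counts in WT, 0.273% ± 0.113 in cuc2-3 (0.177%, 0.244% and 0.398% in cuc2-3 1, 2 and 3) and 0.251% ± 0.028 in the libraries labelled CUC2gm-4 (SD, n = 3), ratios of 2.31 and 2.12 to WT. A 2-sided exact permutation test gave p = 0.1 for each, the smallest that 3 against 3 allow. Against WT 75 of the 77 tested plastid genes had positive log2 fold changes in either mutant, with medians of 1.51 and 1.67. Of single plastid genes ATCG00540 was at 1.45 in cuc2-3 against WT (adjusted p = 1.0; DESeq2 0.019, the lowest of all alternatives), and ATCG00040 at 3.09 in CUC2gm-4 against WT (adjusted p = 0.058; block adjusted p = 0.0015; 1.3e-10 in DESeq2 to 0.328 over all alternatives). Mitochondrial genes took 0.00139%, 0.00156% and 0.00209% of counts in WT 1, 2 and 3 and 0.00455%, 0.00603% and 0.00572% in CUC2gm-4 1, 2 and 3. In cuc2-3 they took 0.00267% and 0.00233% in libraries 1 and 2 but 0.0223% in cuc2-3 3, which sets the mean of that genotype. The library cuc2-3 3, with the largest plastid share too, also had the lowest mapping rate (92.2%). It had the largest share of mapped reads removed for several placements as well (2.61%). The libraries were selected for messenger RNA, and whether that selection kept organelle transcripts to the same extent in every library was not tested. Without replicate 3 of every genotype, a choice made after seeing the data, 8 genes passed in cuc2-3 against WT, 5 of them plastid genes that were higher, and 20 passed in CUC2gm-4 against WT, 14 of them plastid genes that were higher.

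Genes of the circadian clock set some libraries apart within each genotype. A clock index, the mean log2 CPM of 7 clock genes that peak towards dusk minus that of 5 that peak around dawn, was 5.35, 4.84 and 2.70 in WT 1, 2 and 3, then 2.96, 5.42 and 1.67 in cuc2-3 1, 2 and 3, and 5.11, 5.25 and 1.16 in CUC2gm-4 1, 2 and 3. FKF1, an evening-phased blue light receptor, was at 80.6, 62.0 and 12.9 normalised CPM in the WT libraries and at 15.9, 75 and 5.26 in the cuc2-3 libraries. Beside these, the mean log2 CPM of the touch and immediate early genes was 5.0, 4.95 and 4.19 in WT, 3.67, 5.02 and 3.44 in cuc2-3 and 3.20, 4.38 and 3.21 in the libraries labelled CUC2gm-4. The circadian list itself passed in no comparison, with camera adjusted p-values of 0.955, 0.989 and 0.890 in the order given above. That test looks for a shift in 1 direction, and the list mixes dawn and dusk genes, so it can miss a shift of the clock. The median size of the log2 fold change was 0.503, 0.264 and 0.305 in this list, against 0.128, 0.175 and 0.147 in all genes.

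**Figure D3:**
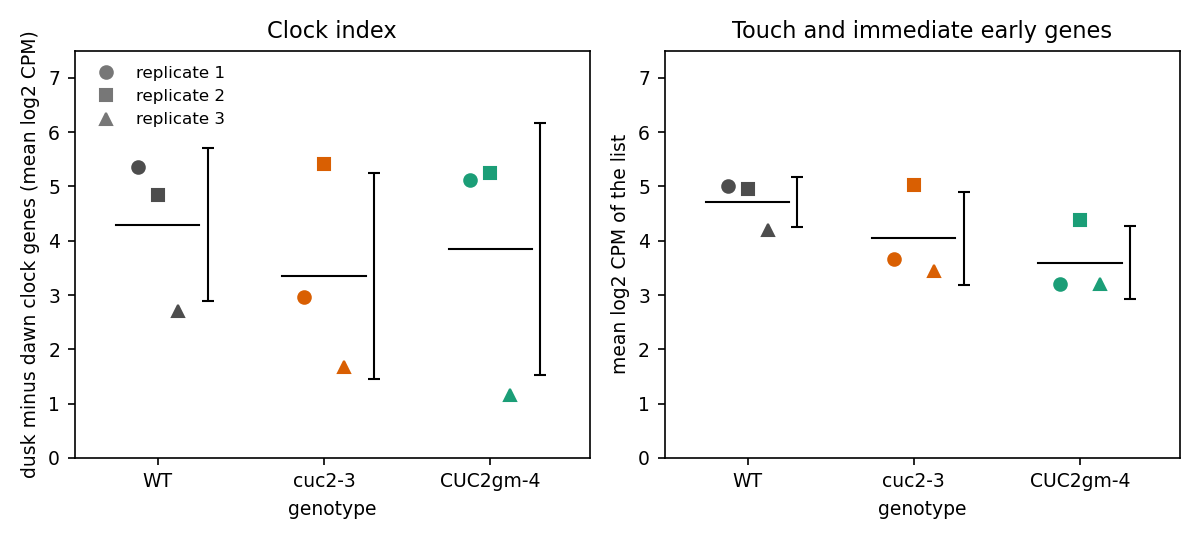
Clock index (left; mean log2 CPM of dusk genes minus dawn genes) and mean log2 CPM of the touch and immediate early list (right) for each of the 9 libraries, with the genotype mean as a line and the SD (n = 3) as a bar to its right. The clock index is lowest in replicate 3 of each genotype (2.70, 1.67 and 1.16), and the touch list mean is lower in the libraries labelled CUC2gm-4 than in the same-numbered WT libraries.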

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

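The clock covariate, the removal of replicate 3 of every genotype and the blocked fits without a library were chosen after seeing the data; the rest was planned. MRD1, AT2G44970, TRM21 and SADHU3-2 kept their calls wherever they were tested, and the cause was not tested for any of the changes given here unless stated. Genes changed in cuc2-3 vs WT (4) became 14 with DESeq2 and 8 without replicate 3 of every genotype, and ranged from 3 to 4 with single libraries left out (3 to 18 around the blocked 4). For CUC2gm-4 vs WT (3) they became 81 with DESeq2, 9 with no count minimum, 35 with the replicate block, 6 with only the genotypes compared, 6 with the clock index and 20 without replicate 3 of every genotype, with a range of 2 to 8 (4 to 94 around the blocked 35). For CUC2gm-4 vs cuc2-3 (3) they became 25 with DESeq2, 7 with the block and 1 without replicate 3, with a range of 2 to 4 (2 to 8 around the blocked 7). Gene lists changed (4, 4 and 5) fell to 0, 0 and 0 both with an estimated correlation and with fry, became 7 with the replicate block and 7 with the clock index for CUC2gm-4 vs WT and 7 without replicate 3 for cuc2-3 vs WT, and ranged from 0 to 8, 4 to 9 and 2 to 7 with single libraries left out. Apart from these and the calls given with each comparison the block changed no other call among the results reported here. Shared calls (2) became 8 with DESeq2 and 7 without replicate 3. CUC2 kept its direction in the comparisons with CUC2gm-4 (3.75 to 4.46 against WT with single libraries left out) and missed the threshold without CUC2gm-4 3 against WT (3.96) and without replicate 3 against cuc2-3 (4.72), where fewer libraries were fitted.

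Reversals were limited to values that passed no test, apart from the touch list. With libraries left out, in cuc2-3 vs WT CYP78A5 ranged from -0.092 to 0.62, STM from -0.17 to 0.72 and MYB117 from -0.80 to 1.09, which limma-voom put at 0.18. In CUC2gm-4 vs WT SADHU3-2 ranged from -0.20 to 1.44, with -0.11 in between. In CUC2gm-4 vs cuc2-3 CUC3 ranged from -0.13 to 0.035 (also 0.020 and 0.026), MRD1 from -0.051 to 0.19 (also -0.033) and AT3G29644 from -0.060 to 0.27 (also -0.0084 and -0.00011), and the touch list's adjusted p from 2.6e-10 to 0.828. CUC3 was at 0.052 with library totals and 0.0076 with the clock index there. Depth limits genes near the floor such as CUC1, MIR164a and SADHU3-2 in WT.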

Other observations

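The tests of gene lists were planned and that of the clock-output genes was set before its values were seen. The other tests of explanations and the splits were chosen after the results were seen. The KNOX homeobox genes that keep the shoot meristem undifferentiated had positive log2 fold changes in the libraries labelled CUC2gm-4 against WT: STM 0.81 (SE 0.61), KNAT1 0.60, KNAT2 1.02 (SE 0.66) and KNAT6 1.01 (SE 0.49), none past the threshold in edgeR's quasi-likelihood test. Their list had 6 of 11 members positive and a camera adjusted p of 0.287. Auxin response genes had 18 of 21 members negative in the same comparison with a median of -0.49, for example IAA29 (-1.20), IAA5 (-1.53) and IAA19 (-0.94), and an adjusted p of 0.051 (0.863 with an estimated correlation). Of the gibberellin synthesis genes GA20OX1 was at -1.01 (SE 0.39) and GA20OX2 at -1.72 (SE 0.78), in a list with a median of 0.054 whose test had the opposite sign (adjusted p = 0.688).

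The leaf polarity list held the HD-ZIP III genes, which specify the upper leaf side, at positive values in the libraries labelled CUC2gm-4 against WT: PHV 0.55, ATHB-15 0.44, PHB 0.40 and REV 0.31 (list adjusted p = 0.223). Genes of the lower side lay on both sides of 0, with KAN at -0.20, KAN2 -0.14, KAN3 -0.23 and YAB5 -0.35 but ETT at 0.27, ARF4 0.34 and YAB2 0.13. The defence genes PR1 (-0.94) and BGL2 (-0.83) were negative in that comparison and positive in cuc2-3 against WT (0.63 and 0.72), with list adjusted p-values of 0.446 and 0.881. Leaf margin and blade growth genes gave an adjusted p of 0.484 in CUC2gm-4 against WT, with ARGOS, a promoter of organ size, at -1.49, and of 0.221 in cuc2-3 against WT, with ARGOS at -1.39.

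Clock genes differed between libraries of a single genotype by more than between genotypes: the smallest range of the clock index within a genotype was 2.65 and the largest difference between genotype means 0.948, which argues against genotype as what sets it. A candidate explanation is that libraries were harvested at different times of day. A second index from 6 dusk and 6 dawn output genes, listed before its values were seen, followed the first over the 9 libraries as deviations from the genotype means with Pearson's r = 0.960 and Spearman's rho = 1, each with an exact permutation p of 0.0046 within genotypes, the smallest that 216 arrangements allow. Without the 2 libraries farthest from the median r was 0.925. Output genes follow the clock whatever shifts it, so this agreement does not tell harvest time from other causes of a shift. The harvest time of each library is not in the labels, so a state of the plants that moves clock genes without a different hour stays open and was not tested.

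Touch and immediate early genes were lower in the libraries labelled CUC2gm-4 than in WT, with a mean log2 CPM of 3.6 ± 0.679 against 4.71 ± 0.455 (n = 3). With the clock index as a covariate the list's median log2 fold change was -0.997, against -1.16 without it. The camera adjusted p there was 8.7e-14 (adjusted p = 0.507 with an estimated correlation). A linear effect of what the index follows thus did not account for most of the fall in this fit. Effects of time of day that the index does not follow stay open. CUC2gm-4 1 and 2 had indexes of 5.11 and 5.25 but list means of 3.20 and 4.38. The list mean was lower in 3 of 3 same-numbered pairs, which does not bear on an effect of the replicate numbers, since each genotype holds every number once. Handling at harvest that differed by genotype could give the same values and cannot be told apart from the genotype, because the labels give no order of harvest. The exact permutation test of the list mean cannot separate them, since both follow the same labels. Its p of 0.2, from a test that ignores the pairing by replicate number, leaves chance open as the source of the difference. The libraries also overlap, with WT 3 at 4.19 and CUC2gm-4 2 at 4.38, which differ in replicate number. A difference that comes with the genotype itself stays open and was not tested apart from handling.

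MRD1 and AT2G44970 were higher in both mutant genotypes by about the same amount, although CUC2 itself was high in only the libraries labelled CUC2gm-4. A graded response to the CUC2 transcript is argued against by the median difference of 0.093 in log2 fold change between the mutants for these 2 genes. A rise of the overlapping HEI10 as the source of the MRD1 reads is argued against, because HEI10 differed from WT by 0.71 at most. AT1G07887, which overlaps MRD1 by 1039 bp on the opposite strand, was not tested, so reads from it stay open. A transcript of the opposite strand confined to the overlap stays open too, since the strand setting of the counting is not given. The 12 flanking genes had log2 fold changes against WT with a median size of 0.13 and a largest of 0.52. A rise as large as that of MRD1 or AT2G44970 shared by these neighbours is thus argued against. HEI10, which overlaps MRD1 and reached 0.71, is not among the 12. A changed interval need not alter the expression of its neighbours, so such an interval stays open. A difference between the seed stocks or parents of WT and of the mutant lines may be the source and was not tested.

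Each comparison of 3 libraries with 3 has 10 splits, so the share of splits as large as the real one is never below 0.05. The real split gave 4, 3 and 3 genes in cuc2-3 against WT, CUC2gm-4 against WT and CUC2gm-4 against cuc2-3, the highest other split 0, 0 and 1, and 1, 1 and 1 splits were as large, the real one included. With the replicate block the real split gave 4, 35 and 7 genes, the highest other 1, 2 and 11, and 1, 1 and 2 splits were as large. The split with 11 genes set CUC2gm-4 1, CUC2gm-4 2 and cuc2-3 1 apart and parted 1 pair of replicate numbers, while the 3 other splits that part all 3 pairs, as the real one does, gave at most 1, 0 and 0. For gene lists the real split gave 4, 4 and 5, the highest other 9, 8 and 10, and 9, 9 and 7 splits were as large. Among the splits that part all 3 pairs the highest other was 8, 8 and 7. The numbers of lists that passed are thus no larger than most other groupings of the same libraries give.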
